A study of Mus musculus with 16 samples.

How the data were processed

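Total RNA from hypothalamus of 16 mice (8 control, 8 KO chimera) was labelled with Cy3 and hybridised to Agilent mouse arrays, 1 animal per array. The authors deposited, for each array, the scanner's intensity per spot as processed by Agilent Feature Extraction 10.7, per the submitters' processing notes; the processed intensity is on a linear scale with background already subtracted, per the file headers. They also deposited a table of log2 values per spot whose normalization is not given in the sources used here. Set against the scanner's own log2 values (above 5), this table gave a correlation across spots of at least 0.9996 on each array and a slope of 0.978 to 1.025, with array medians of 5.21 to 5.26 and a floor of 2.2 that holds 22.3% of its values. Its scale is therefore log2 and its genes were not centred, while the step that aligned the arrays stays unknown. Groups and replicate numbers came from the labels; the title of 1 KO chimera is spelled with a zero in place of the letter O, and its group was taken from the source name.

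Each array held 59305 non-control spots for 55681 probes, and 27276 to 43248 spots per array were well above background. Control spots and spots that the scanner marked as outliers were left out, log2 of the processed intensity was taken, the array's 75th percentile was subtracted, and spots of the same probe were averaged. Probes well above background on at least 8 of the 16 arrays were kept (35144, after 3 with fewer than 4 unmarked values in a group were left out), and for each gene the probe with the highest mean over all arrays was tested (24362 genes, 15482 of them with a gene symbol). Probes were named through their RefSeq accession (28361), current symbol (3186) or older symbol (270), and the other 23864 kept the name in the files. Positions are those in the files, in mm9. Groups were compared with lmFit and eBayes in limma 3.58.1 (R 4.3.3) with Benjamini-Hochberg adjustment and a threshold of 0.05, and every fold change is KO chimera minus control on the log2 scale. A probe well above background on 0 arrays of a group was to be given only a bound, and no gene tested and named in the report was in that state.

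The tests, the gene lists and the rule for the genes named were chosen before the data were examined. There were 41 lists, 17 of cell types and 24 of pathways, tested with camera in limma (preset correlation 0.01), with camera using an estimated correlation, and with fry, each adjusted over the lists. A list score is the mean over members of log2 values centred per gene. The genes named were Adrb1 and Nnt, the 10 genes past the threshold with the largest rise and the 10 with the largest fall among those with a gene symbol, and up to 3 members of each list with the smallest p; further list members named beside them, and the genes in the closing part called so there, were chosen after their values were seen. Some results are not reported here. The arrays lay on 6 slides, 5 of which held both groups. They were scanned on 2 days with 4 animals of each group on each day. Slide and day were tested as blocks and within themselves. Slide 4 held only KO chimera replicate 1 and control replicate 8, and slide 5 only KO chimera replicate 7 and control replicate 5. Differences within these 2 slides therefore compare single animals. The spike-in line of the control replicate 8 array had an R2 of 0 in the scanner's statistics. Alternatives were other normalizations and background corrections, the deposited value table, other filters on dim probes, every probe, blocks for slide, scan day and replicate number, eBayes with trend and robust settings, array weights, each animal left out, a threshold of 0.1, and an exact permutation test over all 12870 assignments of the animals.

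The scripts were tested on simulated data of this comparison with 24362 genes, the real means and spreads, and 200 genes changed by a known amount. Of 67 genes changed by 0.5 on the log2 scale 50.7% were called, of 67 changed by 1 85.1%, and of 66 changed by 2 98.5%, with 11 of 24149 unchanged genes called. A simulated list of 13 genes shifted by −0.3 passed camera, as did 1 other list. The simulated genes were drawn independently of each other, whereas members of the real lists vary together (estimated correlation 0.68 for thalamus). The simulation therefore does not test whether the preset correlation of camera is adequate. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.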

Results

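Gene expression was measured in the hypothalamus of 16 mice on 1-colour Agilent arrays. Of these, 8 were control mice and 8 were called KO chimeras by the submitters. The KO chimeras were C57BL/6J mice that had received 950 Rad of whole-body irradiation, a dose that destroys the animal's own blood-forming cells. They then received marrow from adrenergic receptor knockout mice, given once behind the eye. The labels give a ratio of 1 to 4 (knockout to C57BL/6J) without saying whether it counts donors per recipients or the cells of mixed marrow. Tissue was taken after 2 to 3 months. The labels repeat this treatment word for word for all 16 mice, and their strain field gives irradiated C57BL/6J for all 16 as well. Only the KO chimeras have a field for the strain of the marrow donor, so whether the control mice were irradiated and given marrow of another kind, or neither, is not settled. The title of the study places the work in the question of what the loss of sympathetic input does to bone, hypothalamus and gut. Only hypothalamus was analysed here. Each array held 59305 non-control spots, of which 27276 (KO chimera replicate 1) to 43248 (control replicate 8) were well above background. The number of arrays limits the precision. Each array holds RNA from a separate animal, so p-values measure the spread between these animals. If the ratio counts donors per recipients, KO chimeras shared donors and would not be independent replicates of the donor marrow.

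In KO chimeras, 922 of the 24362 genes tested had changed relative to control (limma, adjusted p under 0.05), 248 of them higher and 674 lower. With quantile normalization 527 genes were called. In models chosen after the data were seen, 9 were called with the thalamus marker score as a covariate and 3 with the oligodendrocyte marker score. Among genes with a gene symbol, those that rose furthest were Ctse and Gdpd3, which lay near background in nearly every control mouse. Among the genes that fell were some genes of myeloid cells (Wfdc17, Itgax, Trem2). Others were genes induced by glucocorticoid hormones (Sgk1, Zbtb16, Tsc22d3) and myelin genes (Mal, Mobp, Cldn11). Itgax and Trem2 did not pass with the slide as a fixed block. The list of border and infiltrating macrophages did not pass (camera adjusted p = 0.687). Most changes were small: the median size among the 922 genes was 0.35 on the log2 scale. In size, 18 of the genes that rose and 10 of those that fell changed by at least 2-fold. The direction was the same in all 5 slides that held both groups for 831 of the 922 genes, which were chosen on these same animals. With the slide as a fixed block 476 genes were called (114 higher, 362 lower), of which 386 were among the 922. With the slide as a random block 1276 were called. Within the first scan day limma called 0 genes (2836 at an unadjusted p under 0.05) and within the second 7 (3431 at an unadjusted p under 0.05), each with 4 mice per group. With normexp background correction in place of the scanner's processed signal, 254 genes were called, 25 higher and 229 lower. By that measure 9.8% of the calls were higher instead of 26.9%. With no filter on dim probes 593 genes were called, 242 higher and 351 lower, or 40.8% higher. Without control replicate 1, 5 or 7 the number of genes was 538, 360 or 358. Without KO chimera replicate 2, 4, 6 or 7 it was 417, 579, 403 or 596.

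Adrb1, which encodes the beta-1 adrenergic receptor and is deleted in the donor marrow, was lower in KO chimeras on 1 of its 2 probes. Adrb1 (chromosome 19, mm9, probe at 56799215 to 56799274) measured −0.70 ± 0.35 in control and −1.45 ± 0.22 in KO chimeras (log2 signal relative to the array's 75th percentile, SD, n = 8 each). Its log2 fold change was −0.75 ± 0.14 (SE; limma adjusted p = 0.0140), and the groups did not overlap. Control replicates 1 to 8 measured −0.86, −0.87, −1.0, −1.06, −0.19, −0.79, −0.13 and −0.68. KO chimera replicates 1 to 8 measured −1.24, −1.55, −1.18, −1.72, −1.71, −1.50, −1.19 and −1.48. This probe kept its call in 33 of 37 alternative settings. With the oligodendrocyte score as a covariate the 3 genes called were Ctse, Gdpd3 and Zbtb16, so Adrb1 did not pass there. The other Adrb1 probe (56797242 to 56797301) gave −2.83 ± 0.18 in control and −2.84 ± 0.19 in KO chimeras, so the probes of this gene disagree. The cells of the recipients' own brain carry the gene intact. The position of the probes relative to the deleted sequence was not analysed here, so these values do not check the labels. Nnt, which carries a deletion in C57BL/6J mice, differed by 0.18 ± 0.06 (limma adjusted p = 0.105).

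**Figure D1:**
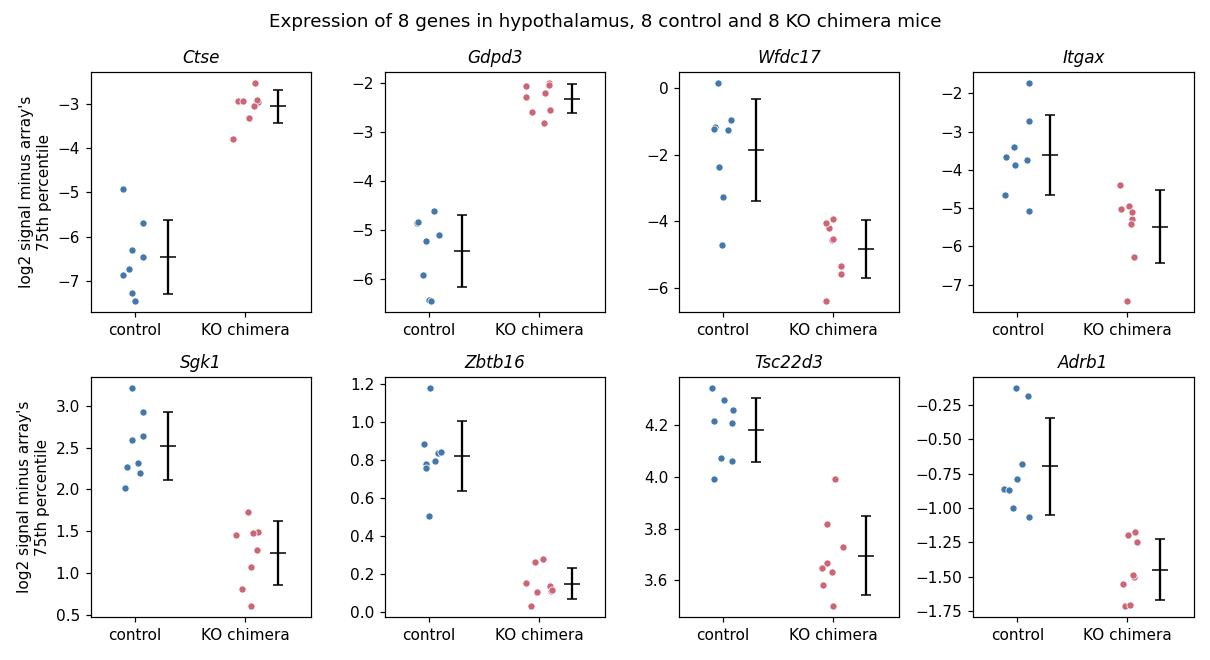
Log2 signal relative to the array's 75th percentile (vertical axes) of 8 genes in each of the 8 control and 8 KO chimera mice; points are animals, and bars show the mean and SD. Ctse and Gdpd3 were higher in every KO chimera than in any control mouse. Sgk1, Zbtb16, Tsc22d3 and Adrb1 were lower in every KO chimera than in any control mouse.

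Ctse, which encodes the aspartic protease cathepsin E, rose by 3.41 ± 0.30 on the log2 scale (SE; limma adjusted p = 3.3e-05), from −6.46 ± 0.83 in control to −3.05 ± 0.37 in KO chimeras (SD, n = 8 each). Gdpd3, a glycerophosphodiester phosphodiesterase, rose by 3.11 ± 0.26 (limma adjusted p = 3.2e-05), from −5.43 ± 0.73 to −2.32 ± 0.30. The groups did not overlap in either gene. Ctse was well above background on 1 of 8 control arrays and Gdpd3 on 2 of 8, and both on 7 of 8 KO chimera arrays. The control level is poorly measured and the fold is uncertain. Among genes with a gene symbol, 8 others made up the 10 with the largest rise. They were Defa-ps1, Ffar2 (a receptor for short-chain fatty acids), Cd300ld4, P2rx6 (a subunit of ATP-gated channels) and Gml. The rest were Lrrc71, Trav3n-3 (a segment of the T cell receptor alpha locus) and Gas2l2. The rise of these 8 lay between 0.88 for Gas2l2 and 1.52 for Defa-ps1 (limma adjusted p between 0.0194 and 0.0472). Their smallest rise over the alternative settings lay between 0.11 for Gml and 0.38 for Lrrc71. Defa-ps1, Ffar2 and Cd300ld4 were well above background on 3 of 8 control arrays, so the size of these rises is uncertain. None of these 8 passed with the slide as a fixed block (limma adjusted p between 0.0632 and 0.110).

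The largest fall was in Wfdc17, a small secreted protein made by macrophages, at −2.98 ± 0.57 (SE, limma adjusted p = 0.0148). It went from −1.85 ± 1.54 in control to −4.83 ± 0.87 in KO chimeras (SD, n = 8 each). Wfdc17 was well above background on 7 of 8 control arrays and 4 of 8 KO chimera arrays. Over the alternative settings its fall was as small as −1.16, so the size is uncertain. Itgax, which encodes the integrin CD11c of dendritic cells and some microglia, fell by 1.88 (limma adjusted p = 0.0363). It was well above background on 7 of 8 control arrays and 1 of 8 KO chimera arrays, so the size of this fall is uncertain, and with normexp background correction it was −0.38 (limma adjusted p = 0.319). Prkcd, a protein kinase C that is abundant in thalamus, fell by 1.87 (limma adjusted p = 0.0431). Sgk1, a kinase induced by glucocorticoids, fell by 1.28, the neurotrophic factor gene Gdnf by 1.14 and Plin4, which coats lipid droplets, by 1.05 (limma adjusted p = 0.00484, 0.00970 and 0.00792). Mctp2, Krt12, Rab37 and Adgrg6 made up the rest of the 10 genes with the largest fall, at −1.68, −1.47, −1.31 and −1.18. With normexp background correction Mctp2, Krt12, Adgrg6 and Gdnf measured −0.54, −0.44, −0.33 and −0.31 and did not pass, and neither did Prkcd and Rab37. With the slide as a fixed block, Itgax and Rab37 no longer passed (limma adjusted p = 0.0588 and 0.0511).

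Genes induced by glucocorticoids were lower in KO chimeras as a group. All 14 measured members had a negative log2 fold change, with a median of −0.27. Of these, 6 fell (12 when adjusted over the list alone). Zbtb16, a zinc finger transcription factor, fell by 0.67 ± 0.08 (SE) and Sgk1 by 1.28 ± 0.18. Tsc22d3, an anti-inflammatory leucine zipper protein, fell by 0.49 ± 0.07. Sult1a1, Klf9 and Fkbp5, the last a co-chaperone of the glucocorticoid receptor, fell by 0.45, 0.40 and 0.26. In limma, Zbtb16 had an adjusted p of 0.000711 and Tsc22d3 of 0.00610. Zbtb16, Sgk1, Tsc22d3 and Sult1a1 also passed with the slide as a fixed block, which Klf9 and Fkbp5 did not (limma adjusted p = 0.0531 and 0.0909). With the oligodendrocyte score as a covariate, Zbtb16 was the only gene of the list still called. The list passed camera with its preset correlation (adjusted p = 2.9e-10; adjusted p = 0.120 with an estimated correlation). The mean difference of the list was −0.25, −0.28, −0.43, −0.35 and −0.56 within slides 1, 3, 4, 5 and 6, and −0.47 and −0.29 within the scan days. Slides 4 and 5 each held a single animal per group, here and for the lists below. With the slide as a block the camera adjusted p was 2.4e-08. Markers of thalamus and of oligodendrocytes were lower in the same animals, with list medians of −0.82 and −0.25.

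**Figure D2:**
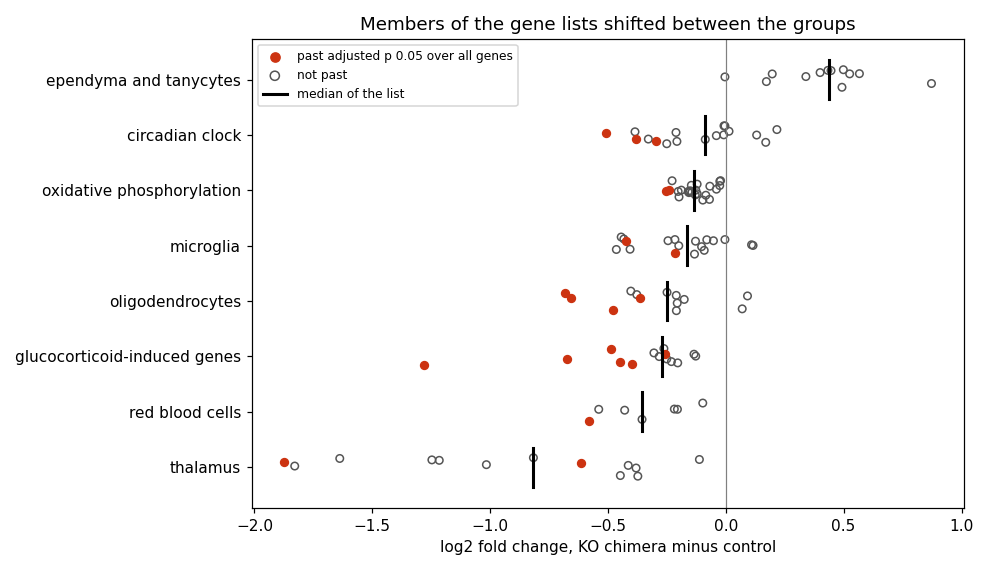
Log2 fold change (KO chimera minus control, horizontal axis) of each measured member of the 8 gene lists that passed camera with a preset correlation, 1 list per row; filled points passed adjusted p 0.05 over all genes, open points did not, and the black line is the list's median. All 14 glucocorticoid-induced genes lie below 0, and the thalamus list has the lowest median, −0.82.

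Genes of oligodendrocytes, the cells that form myelin, were lower in KO chimeras. Of the 13 measured members 4 fell (6 when adjusted over the list alone). Mobp fell by 0.68 ± 0.13 (SE), Mal by 0.66 ± 0.11, Cldn11 by 0.48 ± 0.10 and Mog by 0.36 ± 0.09. Of these only Mog did not pass with the slide as a fixed block (limma adjusted p = 0.0748), and Mbp and Ermn measured 0.07 and 0.09. The 3 Mobp probes gave −0.68, −0.52 and −0.21. The list passed camera (adjusted p = 4.7e-05; adjusted p = 0.435 with an estimated correlation; 2.6e-05 with the slide as a block). Its mean difference was −0.19, −0.33, −0.33, −0.64 and −0.22 within slides 1, 3, 4, 5 and 6 and −0.35 and −0.24 within the scan days. Markers of thalamus, which borders the hypothalamus, were also lower: all 13 had a negative log2 fold change, from −0.11 for Calb2 to −1.87 for Prkcd. Of them Prkcd and Adarb1 fell (5 when adjusted over the list alone), Adarb1 not with the slide as a fixed block (limma adjusted p = 0.0562). Tnnt1 and Ramp3 measured −1.83 and −1.64 without passing (limma adjusted p = 0.133 and 0.0714). The thalamus list passed camera (adjusted p = 7.3e-05; adjusted p = 0.471 with an estimated correlation; 2.6e-05 with the slide as a block). It had differences of −0.47, −0.95, −0.79, −1.06 and −0.93 within slides 1, 3, 4, 5 and 6 and −0.93 and −0.91 within the scan days. Ependyma and tanycyte genes were higher as a group, with a median of 0.44 over 12 members and adjusted p = 0.00116 in camera (adjusted p = 0.435 with an estimated correlation; 0.0103 with the slide as a block). Singly 0 members passed, over all genes or over the list alone, and the largest values were 0.87 for Col23a1 and 0.57 for Ccdc153. With the oligodendrocyte score as a covariate neither the ependyma list nor the thalamus list passed camera (adjusted p = 0.569 and 0.119). The difference of the ependyma list was 0.15, 0.58, 0.49, 0.57 and 0.07 within slides 1, 3, 4, 5 and 6 and 0.30 and 0.52 within the scan days.

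Microglia genes were lower in KO chimeras. Of the 18 measured members 2 fell. Trem2, a lipid-sensing receptor of microglia, fell by 0.42 ± 0.09 (SE; limma adjusted p = 0.0216). When adjusted over the list alone 5 passed. Tyrobp, the signalling partner of Trem2, measured −0.43 (limma adjusted p = 0.0522), and Csf1r measured −0.00 (limma adjusted p = 0.979). Trem2 did not pass with the slide as a fixed block (limma adjusted p = 0.0685). The list passed camera (adjusted p = 0.00262; adjusted p = 0.435 with an estimated correlation; 0.00157 with the slide as a block). It did not pass with the oligodendrocyte score as a covariate (0.227) or within scan day 2 (0.168), and thalamus and oligodendrocyte markers were lower in the same animals (medians −0.82 and −0.25). Its difference was −0.12, −0.13, −0.18, −0.30 and −0.28 within slides 1, 3, 4, 5 and 6 and −0.26 and −0.12 within the scan days. Among 11 complement genes, C1qc, a part of the initiating complex that microglia make, fell by 0.36 (limma adjusted p = 0.0430; 0.0819 with the slide as a fixed block). Adjusted over the list alone 5 passed (2 higher, 3 lower), and the list did not pass (camera adjusted p = 0.333). Border and infiltrating macrophages, neutrophils, and T and B lymphocytes had camera adjusted p of 0.687, 0.807 and 0.506. They held 0 members past adjusted p 0.05 over all genes, and 1 lymphocyte gene, higher, passed when adjusted over the list alone.

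Red blood cell genes were lower in KO chimeras, with a median of −0.36 over 7 members. Hbb-b2, a haemoglobin beta chain, fell by 0.58 ± 0.12 (SE; limma adjusted p = 0.0219; 0.0635 with the slide as a fixed block), and 4 members passed when adjusted over the list alone. The list passed camera (adjusted p = 0.00331; adjusted p = 0.435 with an estimated correlation; 0.0339 with the slide as a block). It did not pass within scan day 1 alone. It had differences of −0.42, −0.21, −0.26, 0.13 and −0.49 within slides 1, 3, 4, 5 and 6 and −0.28 and −0.42 within the scan days. Oxidative phosphorylation genes were also lower by a small amount, all 24 with a negative log2 fold change and with a median of −0.14. Atp5b and Ndufa4 fell by 0.25 and 0.24 (limma adjusted p = 0.0410 and 0.0417; 5 passed when adjusted over the list alone). Neither passed with the slide as a fixed block (limma adjusted p = 0.0680 and 0.0698). That list passed camera (adjusted p = 1.6e-05; adjusted p = 0.471 with an estimated correlation; 8.8e-06 with the slide as a block). Markers of thalamus and of oligodendrocytes were lower in the same animals (list medians −0.82 and −0.25). With either score as a covariate the oxidative phosphorylation list still passed camera. Its score gave differences of −0.17, −0.05, −0.00, −0.12 and −0.25 within slides 1, 3, 4, 5 and 6 and −0.16 and −0.11 within the scan days. Of 17 circadian clock genes, Ciart fell by 0.51 ± 0.09, Cry2 by 0.38 ± 0.07 and Nr1d2 by 0.30 ± 0.08 (5 passed when adjusted over the list alone). The core activator Arntl measured −0.00 and Per2 0.17 without passing. The second Cry2 probe gave 0.16 (limma adjusted p over all probes = 0.585), so the probes of this gene disagree, and the second Nr1d2 probe gave −0.18 (0.303). The clock list had an adjusted p of 0.0256 in camera (adjusted p = 0.435 with an estimated correlation; 0.0339 with the slide as a block) and a median of −0.09. It had differences of −0.03, −0.11, −0.21, −0.27 and −0.12 within slides 1, 3, 4, 5 and 6 and −0.18 and −0.08 within the scan days. The clock list was not past the threshold without control replicate 5, 7 or 8 or KO chimera replicate 8 (camera adjusted p = 0.0574, 0.0656, 0.0646 and 0.0771). Nor did it pass with only probes above background on all arrays (0.0690), with array weights (0.0788), without slide 4 (0.0639) or within scan day 2 (0.177). With the thalamus score as a covariate its median was 0.0017 (camera adjusted p = 0.809), and with the oligodendrocyte score −0.06 (0.569).

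**Figure D3:**
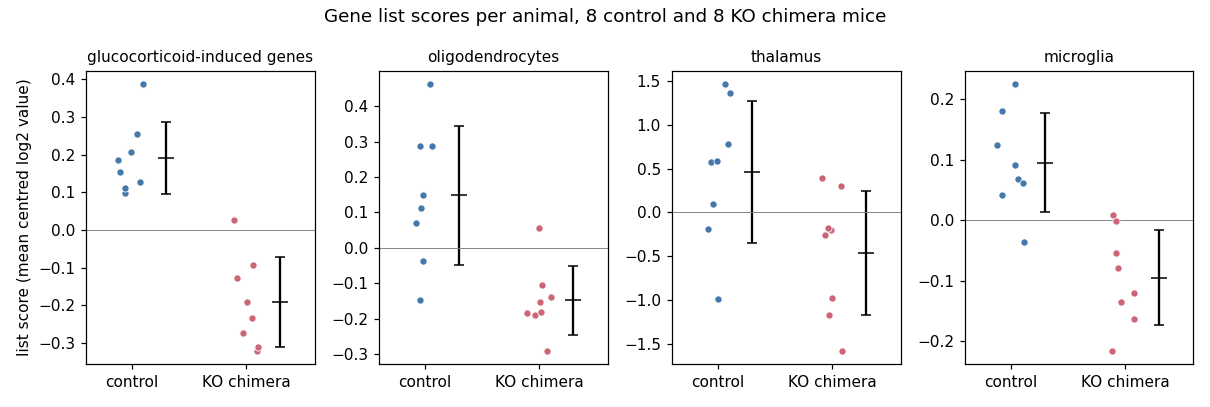
Score of 4 gene lists (vertical axes: the mean over members of log2 values centred per gene) in each of the 8 control and 8 KO chimera mice; points are animals, and bars show the mean and SD. The glucocorticoid score was 0.19 ± 0.10 in control and −0.19 ± 0.12 in KO chimeras, and its values did not overlap between the groups, whereas the thalamus scores did.

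The other lists did not pass camera with the preset correlation, and 0 of all 41 lists passed with an estimated correlation (lowest adjusted p = 0.120). Of the 8 lists past camera, thalamus and ependyma did not pass fry (adjusted p = 0.0865 and 0.0715). The other 6 did, as did glutamate and GABA receptors (0.0126) and p53 targets (0.0154). Hypothalamic neuropeptides (camera adjusted p = 0.124) and hypothalamic transcription factors (0.194) had medians of 0.16 and 0.15, with 0 members past the threshold over all genes (1 transcription factor, higher, when adjusted over the list alone). Pomc measured 0.59 (limma adjusted p = 0.168) and Cck −1.17 (limma adjusted p = 0.0940). Monoamine and acetylcholine synthesis (camera adjusted p = 0.807), adrenergic receptors (0.687), cAMP signalling downstream of beta-adrenergic receptors (0.333) and the renin-angiotensin and vasopressor system (0.506) did not pass. Adrb1 was the only one of their members that did. Among inflammatory lists, cytokines and chemokines (0.807), cytokine receptors and innate signalling (0.981), MHC class I and antigen presentation (0.199), MHC class II (0.0802) and interferon response (0.407) held 0 genes past adjusted p 0.05 over all genes. By list alone 1 cytokine gene, higher, passed. For p53 targets the camera adjusted p was 0.148, and 1 of 13, Zmat3, fell (−0.31, limma adjusted p = 0.0160). Cell cycle (0.341), immature neurons and progenitors (0.194), hypoxia and tissue handling (0.506, with 1 lower member when adjusted over the list alone), heat shock and unfolded protein response (0.871, with Atf4 at −0.26, limma adjusted p = 0.0430) and cytosolic ribosomal proteins (0.807) did not pass. The second Atf4 probe gave −0.06 (limma adjusted p over all probes = 0.758). Immediate early genes (0.148) included Arc, which fell by 0.44 (limma adjusted p = 0.0396). Ionotropic glutamate and GABA receptors (0.148) included Gabra3, which fell by 0.35 (limma adjusted p = 0.0158; 5 members passed when adjusted over the list alone). The other Gabra3 probe gave 0.11 (limma adjusted p over all probes = 0.759).

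Of the lists for other cell types and neighbouring tissue, astrocytes (camera adjusted p = 0.148) held Fgfr3, which fell by 0.34, and Slc4a4, which rose by 0.27 (limma adjusted p = 0.0284 and 0.0489; 3 members passed when adjusted over the list alone). The other Slc4a4 probes gave 0.32 and −0.38, so the probes of this gene disagree. The second Fgfr3 probe gave −0.12 (limma adjusted p over all probes = 0.596). General neurons (0.113) held Rbfox3, which fell by 0.26 (limma adjusted p = 0.0442), and whose other probes gave −0.15 and −0.19. Cortex and hippocampus (0.199) held Rtn4r and Cux2, which fell by 0.85 and 0.54 (limma adjusted p = 0.0394 and 0.0490; 4 members passed when adjusted over the list alone). Oligodendrocyte precursors (0.807), endothelium and mural cells (0.333), choroid plexus (0.506), meninges and fibroblasts (0.0993), pituitary (0.807), striatum (0.365) and sex-linked genes (0.807) held 0 members past adjusted p 0.05 over all genes. Adjusted over the list alone, 3 members of striatum, 1 of choroid plexus and 1 of oligodendrocyte precursors passed. The direction that camera gave differed in sign from the median for choroid plexus, T and B lymphocytes, pituitary, sex-linked genes, and cytokine receptors and innate signalling. It differed from the mean for choroid plexus, neutrophils, pituitary, and cytokine receptors and innate signalling. Of the genes of these 33 lists that passed, Atf4, Arc, Slc4a4, Cux2 and C1qc did not pass with the slide as a fixed block (limma adjusted p = 0.0589, 0.0789, 0.104, 0.0639 and 0.0819).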

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

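Each gene list score and a set of single genes were examined for an animal that stood apart from the others of its group. The set did not hold every gene named in the report. The measure was the gap to the nearest other animal as a share of the group's range. An animal stood apart in 9 of 188 groups of 8, and chance gives about 1 in 20. All values below are on the log2 scale, relative to the array's 75th percentile for genes and centred per gene for list scores. Rarres2, a gene of the ependyma and tanycyte list, was lowest in control replicate 6, at 1.55, with the nearest other animal at 2.38. In KO chimera replicate 1 the choroid plexus score was 1.55 against 0.33 in the nearest animal, and the score of the renin-angiotensin and vasopressor system was −0.22 against −0.01. KO chimera replicate 4 had the highest score for meninges and fibroblasts, 1.04 against 0.24, and for interferon response, 0.45 against 0.11. General neuron genes were highest in control replicate 5, at 0.25 against 0.10. The immediate early gene score was lowest in KO chimera replicate 6, at −0.37 against −0.17, and that of cytosolic ribosomal proteins in KO chimera replicate 8, at −0.17 against −0.03. Sex-linked genes were highest in KO chimera replicate 3, at 0.41 against 0.09.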

How the results depend on the processing

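Of the settings below, the thalamus and oligodendrocyte scores as covariates, the single scan days and the removal of slide 4 were chosen after seeing the data. The number of genes called was 922. It was 527 with quantile normalization, 254 with normexp background correction and the 75th percentile, 484 with normexp and quantile normalization, 535 with the deposited value table, 593 with no filter on dim probes (34598 genes tested), 476 with the slide as a fixed block and 2012 at a threshold of 0.1. It was 9 with the thalamus score as a covariate, 3 with the oligodendrocyte score, 0 within scan day 1 and 7 within scan day 2; the single days hold fewer animals, and the cause of the other changes was not tested. Other settings gave 886 (both arrays of slide 4 left out) to 1276 genes. Leaving out 1 animal gave 358 to 1026 genes and 7 to 10 lists; without control replicates 1, 5 and 7 there were 538, 360 and 358 genes, and without KO chimera replicates 2, 4, 6 and 7 there were 417, 579, 403 and 596. The number of lists past the threshold was 8, with 13 when dim probes were kept, 0 with an estimated correlation and 6 with either score as a covariate. Of the 7 lists other than the covariate's own, 6 still passed with the thalamus score and 3 with the oligodendrocyte score. With the latter thalamus, ependyma and tanycytes, microglia and circadian clock did not pass (adjusted p = 0.119, 0.569, 0.227 and 0.569). The replicate block, fitted because both groups carry numbers 1 to 8, gave 789 genes, and 1746 with the slide as a random block added. Deviations of same-numbered animals correlated at −0.07 to 0.24, above 0.1 in 3 of 8 pairs. In 2 of 8 pairs the animals correlated best with their own number in both directions. No chance level was computed for these values, so they do not settle whether the numbers pair the animals. None of the genes carried through the settings that passed changed direction. Ctse and Gdpd3 kept their call in 35 of 36 settings, all but scan day 1 alone (limma adjusted p = 0.297 and 0.203 there). Their rise was 0.63 to 3.74 for Ctse and 0.76 to 3.37 for Gdpd3. With only probes well above background on all 16 arrays these genes were not tested. Zbtb16 kept its call in 36 of 37 settings, Sgk1 and Tsc22d3 in 33 of 37, Itgax in 16 of 36 and Prkcd in 13 of 37. Signal near background limits both directions: under normexp the rise of Gml was as small as 0.11, and Itgax, Gdnf, Krt12 and Adgrg6 measured −0.38, −0.31, −0.44 and −0.33 with the 75th percentile.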

Other observations

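In the tests below, those on positions along the chromosomes, on the spread of macrophage genes and on oligodendrocytes as the whole cause were chosen after the results were seen, as were the genes named in this part that the report does not name. Ccl6, a chemokine of myeloid cells, fell by 0.64 and Cd68, a lysosomal protein of macrophages, by 0.53 (limma adjusted p = 0.0149 and 0.0216). Lgals3, Lyz2, Clec7a and Cybb, also made by phagocytes, did not pass (limma adjusted p = 0.543, 0.254, 0.621 and 0.903). Rab7b, which lies beside Ctse on chromosome 1 (probe at 133609965, against 133571990 for Ctse), fell by 0.82 (limma adjusted p = 0.0216), opposite to Ctse. Genes of tissue next to the hypothalamus varied widely within both groups: the choroid plexus gene Ttr ranged from −2.03 to 5.68 in control and from −1.66 to 5.34 in KO chimeras, and the pituitary hormone gene Prl, well above background on 4 of 8 arrays of each group, from −6.27 to −1.19 and from −7.29 to −2.44.

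When the 16 animals were split into 8 and 8 in 100 ways, 1 split, the real one, gave as many as 922 genes, and the highest of the others gave 0. A split by scan day gave 125 genes, so the day separates the arrays to a smaller degree, and with the day as a block 958 genes were called.

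Tissue composition and the arrays were examined as possible sources of the fall of glucocorticoid-induced genes, and other sources were not tested. The list score differed by −0.38 between the groups (95% interval −0.50 to −0.27). With the slide in the model the difference was −0.39 (−0.53 to −0.24) and with the thalamus score −0.36 (−0.50 to −0.22). Both intervals lay beyond 50% of the unadjusted difference, −0.191. This argues against the slide as the whole cause, and against thalamus content as far as its score captures it. With the oligodendrocyte score the difference was also −0.36, with an interval of −0.531 to −0.186. This excludes 0, which argues against fewer oligodendrocytes, as far as the score captures them, as the whole cause. The interval does not stay beyond the 50% bound, so a contribution of that size stays open. Within the groups the glucocorticoid score correlated with the thalamus and oligodendrocyte scores at r = 0.173 and 0.111. Marker scores measure tissue content with error, so these models cannot exclude a part that the scores miss. Of the single genes of the glucocorticoid list, only Zbtb16 was still called with the oligodendrocyte score. The circadian clock list was also lower in the same animals. A lower response to glucocorticoids in animals with receptor-deficient marrow stays a hypothesis, and hormone levels were not analysed here. The labels do not settle whether the control mice were irradiated and given marrow.

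Ctse and Gdpd3, on chromosomes 1 and 7, were measured in KO chimeras and lay near background in control. With normexp background correction they still passed, with a smaller rise of 0.75 and 0.88, so the size of the rise depends on how background is treated. Over all called genes, 219 neighbouring pairs lay within 500 kb, against a median of 252 in 10000 permutations. Among genes called at 2-fold or more there were 2 such pairs against a 95th percentile of 1 (permutation p = 0.0234), Wfdc17 with AI662270 and Rab37 with Cd300ld4. Neither pair holds Ctse or Gdpd3. Rab7b, the called gene beside Ctse given above, changed by less than 2-fold, so the cutoff kept it out of the second count. These counts do not settle the source of the rise of Ctse and Gdpd3. Marrow-derived cells that express both genes may be the source, which stays open and untested, since the labels do not say whether control mice received marrow.

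Some macrophage genes varied more between control animals than between KO chimeras, and others did not. Lyz2 had an SD of 1.80 in control and 0.37 in KO chimeras, Ms4a7 1.44 and 0.19, and Clec7a 1.06 and 0.10, each with control replicate 2 lowest and control replicate 6 highest. Of the 9 members of the list of border and infiltrating macrophages 5 had the larger SD in control, and 4 had it in KO chimeras (F13a1 0.38 and 0.54, Plac8 0.58 and 0.81, Cbr2 0.36 and 0.71, Cd14 0.15 and 0.18), as did Lgals3 (0.21 and 0.41) and Ccl6 (0.25 and 0.27). The spread of the list's score (SD 0.44 and 0.19) did not differ past the threshold (two-sided exact permutation p = 0.107, mean absolute deviation from the group median). Blood left in the tissue would raise this score along with that of red blood cells, but over the 8 controls they went in opposite directions (Pearson r = −0.671, exact permutation p = 0.0774, adjusted p = 0.155; Spearman rho = −0.810, exact permutation p = 0.0218; r = −0.565 without the 2 animals farthest from the median). The slide and dim arrays stay open as possible sources: the SD was 0.29 over the 3 controls of slide 3 (95% interval 0.149 to 1.79), and the score's correlation with the number of spots well above background was r = 0.275 (exact permutation p = 0.518, adjusted p = 0.518; rho = 0.071, exact permutation p = 0.882; r = −0.422 without the 2 farthest). Different amounts of marrow-derived cells between control animals are a further candidate explanation, which was not tested.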
